A study of Homo sapiens with 160 samples.

How the data were processed

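Total RNA of BEAS-2B cells was sequenced after 8 treatments at 4 times, with 5 replicates planned per group. Per the labels' protocols, the cells were grown to confluence and kept in serum-free medium overnight before treatment, libraries were made with a TruSeq kit, and 2 sequencing kits were used on a NextSeq instrument, without a record of which sample used which. The submitters' processing notes name bcl2fastq 2.17.1.14, STAR 2.4.2a and the genome GRCh38. The quantifier, its annotation, the use of strand and the scaling between libraries are not given in the sources used here.

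The deposited values number 1 per gene and library, for 29273 genes. The authors call these values TPM, but the columns sum to between 847289 and 1498420 (median 961146), while the median ratio of each library to the geometric mean over libraries lies between 0.928 and 1.11. The values were therefore taken as a normalised signal as deposited by the authors, not as TPM and not as counts, although the design fixed before the data were examined had assumed TPM. The planned test, on log2(value + 1), fits both. Depth is unknown, so no counting interval or detection limit is given, and precision is judged from the spread between replicates. A value of 0 is reported only as listed at 0.

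Columns were matched to samples by treatment, replicate and time in their headers. 4 columns are marked as excluded by the authors and were not used. A further 6 are headed with a time of 8 h, which no sample label gives, and were not used. They name replicate 1 of vehicle, of mometasone and of the 4 combinations, the 6 treatments without a matched replicate 1 at 18 h, so they may be those samples. Counts and group sizes at 18 h are without them. This left 150 of the 160 samples, and groups of 3 to 5 libraries. Treatments, times and replicate numbers come from the labels.

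Genes with a value of at least 1 in at least 5 libraries were tested, which kept 14827 genes and left out 14446. Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8), as 1 linear model with a coefficient for each of the 32 groups, 118 residual degrees of freedom, and eBayes with a mean-variance trend. All adjusted p-values of genes are from limma with Benjamini-Hochberg adjustment within each comparison and time, and a gene is called at an adjusted p below 0.05. The 6 main comparisons were carbachol, indacaterol, their combination and mometasone, each against vehicle, the interaction of indacaterol and carbachol, and all 3 agents against indacaterol with carbachol, each within a time. Fold changes are 2 to the power of the log2 change.

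For 5 of these comparisons, all but the combination against vehicle, the genes named were fixed by a rule before the data were examined. It takes the 12 largest rises and 8 largest falls at any time among called genes whose same-numbered replicates all differ in the same direction, up to 4 members of a gene list with the largest absolute log2 change in the comparison and time described, and receptor genes of the agents. Some genes that the rule takes are not reported here. Other names are said to be chosen after values were seen. Gene coordinates were taken from GENCODE 29 on GRCh38, where 27927 of the 29273 symbols matched. CCN2 and MARCHF10 were not matched there.

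The 22 gene lists, also fixed beforehand, were tested with limma's camera, which compares a list with all other genes, at a preset correlation between genes of 0.01 and again with an estimated one. P-values were adjusted over all 528 tests of lists, comparisons and times. Of these, 154 passed with the preset correlation and 64 with the estimated one, all 64 among the 154. Several lists share members. The largest changes of single carbachol genes were also tested with an exact two-sided permutation test, computed over all splits with numpy. Overlaps were compared with that of independent lists. The correlation of carbachol and indacaterol changes was compared with 100 simulations of unchanged groups. For each replicate number, different libraries of that time were drawn from any treatment. Their deviations from the group means stood for a shared vehicle, carbachol and indacaterol. The correlation was computed again with the real vehicle libraries divided between the comparisons by replicate number. The 2 lowest numbers served 1 comparison and the others the second, and then the reverse. Same-numbered libraries deviate together, so this division also sets replicate numbers against each other and cannot isolate the shared vehicle. Added after the data were seen, genes called higher in 2 comparisons with the same vehicle libraries were counted in the same way.

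Replicate numbers come from the sample titles, and nothing in the labels says what a number stands for. They were taken to pair samples in a comparison where, with at least 3 pairs, every pair of same-numbered libraries correlated above 0.1 in its deviations from the group means. This held in 16 of the 24 comparisons and times. The limit was fixed beforehand, but counts of calls with a block had been seen before the check was run. Over all groups of 1 time the median correlation was 0.346 for the same number and -0.0700 for different numbers, and the first principal component of the deviations held 43.0% of their variance, with 83.6% of it between numbers. The reported fit has no block. A fit with the number as a block is given beside a result where the pairing held and the count moved by more than 1.5 times. It is also mentioned for the interaction at 1 h, where the pairing did not hold.

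The model was tested on simulated data for carbachol against vehicle at 1 h, with 200 of 14827 genes changed. It recovered 28.4% of 67 genes changed by a log2 of 0.5, 79.1% of 67 changed by 1 and 93.9% of 66 changed by 2, and 4 of its 138 calls were unchanged genes. The simulated noise was independent between genes and between libraries. The real deviations are not, so these shares and false calls need not hold for the real data. Libraries were compared before averaging: correlations within a group ran from 0.938 to 0.990, and 0 pairs were identical. Alternatives were another pseudocount, no filter or a stricter one, rescaled libraries, a replicate block, separate fits per time, and each replicate left out in turn. 3 more were added after the data were seen: leaving out libraries with a high mitochondrial share, library composition as covariates, and fits of the compared groups only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.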

Results

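Gene expression was measured by RNA sequencing in BEAS-2B cells, an immortalised human bronchial epithelial cell line. The cells received vehicle or 1 of 7 treatments made from 3 agents: mometasone, a glucocorticoid used in inhaled asthma therapy, at 100 nM; indacaterol, a long-acting β-agonist bronchodilator, at 100 nM; and carbachol, an agonist of acetylcholine receptors, at 10 µM. Each agent was given alone, in each pair and as all 3 together, and RNA was collected at 1, 2, 6 and 18 h. The series has 160 samples in 32 groups of 5 replicates, and values of 150 of them were compared. 24 groups held 5 libraries, 6 held 4, and 2 (mometasone alone and all 3 agents, both at 18 h) held 3. At 1 h mometasone alone and all 3 agents had no library of replicate 5. A library had 12521 to 13239 genes at a value of 1 or more, with a median of 12762. Read depth is not recorded in these values and is unknown. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Fold changes are on the log2(value + 1) scale, which understates the change of low genes.

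Markers of 2 of the agents matched the treatment labels. TSC22D3 (GILZ), a gene that the glucocorticoid receptor switches on directly, lay between 53.7 and 453 in the mometasone libraries at 1 h and between 5.37 and 13.9 in all other libraries of that time. The ranges did not overlap at 2, 6 or 18 h either. NR4A3, an orphan nuclear receptor gene that cyclic AMP induces, separated the libraries with indacaterol from those without at 1, 2 and 6 h, with 5.98 to 142 against 0.22 to 3.3 at 1 h, and the ranges overlapped at 18 h. Of the receptor genes, NR3C1, which encodes the glucocorticoid receptor, had a mean of 39.3 over all libraries (range 13.5 to 88.5). The muscarinic receptor genes were lower, with means of 1.24 for CHRM3 (0.4 to 2.62), 0.508 for CHRM4, 0.106 for CHRM5, 0.0863 for CHRM2 and 0.0426 for CHRM1. CHRM3 was the only 1 of these 5 that passed the filter on low values, and its log2 change with carbachol at 1 h was 0.02 (SE 0.15, adjusted p = 1).

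Carbachol alone raised a small set of early response genes within 1 h. NR4A1, an orphan nuclear receptor gene induced by many stimuli (GRCh38 chromosome 12, 52022832 to 52059507, plus strand), rose 5.59-fold at 1 h, from 11.9 ± 3.24 to 73.5 ± 31.9 (SD, n = 5 each). FOSB, which encodes a subunit of the AP-1 transcription factor (chromosome 19, 45467995 to 45475179, plus strand), rose 4.58-fold, from 1.10 ± 0.428 to 11.4 ± 12 (SD, n = 5 each), where replicate 3 stood at 32.75. CCN2, a matricellular protein gene (CTGF), rose 2.53-fold from 238 ± 97.2 to 619 ± 316 (SD, n = 5 each). At 2 h NAB2, a co-repressor of EGR transcription factors (chromosome 12, 57088894 to 57095476, plus strand), rose 2.05-fold from 43.1 ± 8.78 to 88.1 ± 6.53 (SD, n = 5 each). In limma the log2 changes were 2.48 for NR4A1 (SE 0.25, adjusted p = 6.49e-13), 2.19 for FOSB (SE 0.28, adjusted p = 2.78e-08), 1.34 for CCN2 (SE 0.23, adjusted p = 2.37e-04) and 1.04 for NAB2 (SE 0.14, adjusted p = 3.58e-07).

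The other genes of the naming rule rose by less. At 1 h these were IER2 (log2 0.97) and JUNB (0.95), both immediate early genes, and DUSP5 (0.93), a nuclear phosphatase that acts on ERK. PER1 (0.93), a circadian clock gene, LURAP1L (0.73) and HBEGF (0.68), an EGF receptor ligand, also rose at 1 h. At 2 h MIDN (0.85) and RNF227 (0.62) rose. NR4A1 was still 2.45-fold higher at 2 h (log2 1.30, SE 0.25, adjusted p = 0.00616), with 34.6 ± 7.70 against 13.8 ± 4.45 (SD, n = 5 each), and its log2 change at 6 h was 0.17. As the naming rule requires, all 12 genes were higher with carbachol in 5 of 5 same-numbered pairs. An exact two-sided permutation test over the 252 splits of 5 against 5 is no independent evidence for these genes, which were chosen for the difference. It gave p from 0.00794, the smallest it can give (0.0106 adjusted over these 12 genes alone), to 0.0476 for IER2, and the ranges of the carbachol and vehicle libraries overlapped for CCN2, IER2 and RNF227. The values of EGR1 differed widely between libraries, with 241 ± 234 against 58.1 ± 44.0 at 1 h (SD, n = 5 each), and its log2 change of 1.44 (SE 0.58, adjusted p = 1) did not pass. ATF3, a stress-induced transcription factor gene, had a log2 change of 1.06 and did not pass either (adjusted p = 0.0618).

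In all, limma called 12 genes higher and 0 lower at 1 h, and 4 higher and 0 lower at 2 h. Beside the named genes, 3 further genes made up the calls at 1 h and were looked at after their values were seen: GADD45A (log2 0.59, adjusted p = 0.00269), and the pseudogenes SPINT5P (1.35) and SNRPGP3 (0.99), which were higher in 3 of 5 pairs only. At 6 h limma called 0 genes, with 124 at an unadjusted p below 0.05. Unchanged genes in a calibrated test would give more, a share of 0.05 of the 14827 genes tested. Such counts are therefore no sign of remaining changes, and 0 calls here are no evidence that none occurred. The same holds for the other counts at an unadjusted p given below, except the 1520 of the interaction at 1 h. At 18 h limma called 1, the pseudogene SNRPGP17 (log2 0.84, SE 0.17, adjusted p = 0.0271), higher in 3 of 4 pairs. With the replicate number as a block, which the pairing check allows at 2, 6 and 18 h, the counts became 23, 1 and 1. The calls of LURAP1L, HBEGF and MIDN ended without any 1 of the 5 replicates, those of IER2 without replicate 1, 3 or 5, those of RNF227 without replicate 2, 3 or 5, those of JUNB and PER1 without replicate 1 and that of DUSP5 without replicate 3. The calls of IER2, LURAP1L and HBEGF also ended without the libraries with over 20% mitochondrial RNA, and that of HBEGF with a pseudocount of 0.1. The count at 1 h ran from 5 to 9 with 1 replicate left out, fell to 3 with each time fitted alone, and was 0 when only the carbachol and vehicle libraries were fitted. At 2 h it fell to 1 and 0 in the same fits.

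**Figure D1:**
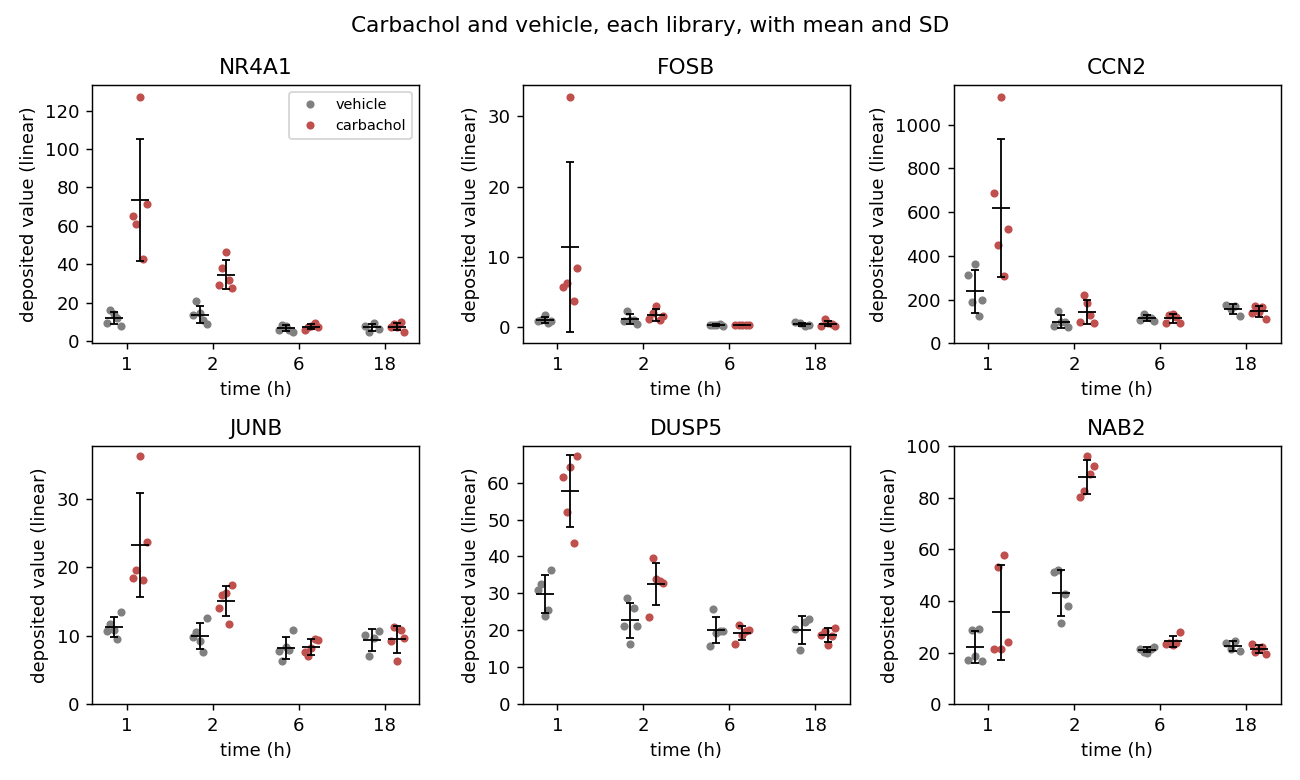
Deposited values (linear axes) of NR4A1, FOSB, CCN2, JUNB, DUSP5 and NAB2 in each vehicle and carbachol library at 1, 2, 6 and 18 h of treatment, with 1 point per library and bars for the mean and SD. NR4A1 at 1 h had a mean of 11.9 with vehicle and 73.5 with carbachol, and FOSB spread more widely, with 1 carbachol replicate at 32.75.

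Of 22 gene lists fixed before the data were examined, the immediate early genes moved most with carbachol at 1 h: 4 of 22 measured members rose and 0 fell, or 13 and 0 adjusted over the list alone (camera adjusted p = 5.15e-50, and adjusted p = 1.21e-07 with an estimated correlation). At 2 h, 1 member, NR4A1, rose, or 3 adjusted over the list alone (camera adjusted p = 3.77e-10, and adjusted p = 0.0487 with an estimated correlation, but 0.0965 with that and the replicate block). Of the genes known to respond to cyclic AMP and CREB, 3 of 19 rose at 1 h, or 6 adjusted over the list alone (camera adjusted p = 3.09e-17, and 0.00398 with an estimated correlation). These were NR4A1, FOSB and PER1, and the first 2 of them also belong to the immediate early list. Among 13 calcium and NFAT genes 1 rose at 2 h, or 2 adjusted over the list alone (camera adjusted p = 4.05e-07, and 8.64e-06 with an estimated correlation). At 1 h that list's median log2 change was -0.02 while its mean was 0.20 and its test pointed up (camera adjusted p = 0.00109, and 0.00527 with an estimated correlation). The 1 member called at both times was NR4A1, which also belongs to the immediate early and cyclic AMP lists, so these 3 lists are not independent of it. Of 12 cytokine genes 0 passed limma at 1 h over all genes or adjusted over the list alone, while the list as a whole moved up (median log2 0.36, camera adjusted p = 3.20e-04, and 0.0285 with an estimated correlation). Of 15 genes of ERK feedback 1 rose at 1 h, DUSP5, both over all genes and adjusted over the list alone (camera adjusted p = 4.09e-05, and adjusted p = 0.212 with an estimated correlation). Of 11 genes of NF-κB feedback 0 rose at 2 h, or 1 adjusted over the list alone (camera adjusted p = 1.20e-04, and 0.0130 with an estimated correlation).

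Indacaterol alone raised more genes, with known targets of cyclic AMP among the largest changes. NR4A3 (chromosome 9, 99821855 to 99866891, plus strand) rose 41.1-fold at 2 h, from 0.412 ± 0.135 to 61.4 ± 25.5 (SD, n = 5 each; log2 5.36, SE 0.30, adjusted p = 1.88e-31). IL6, the gene of the inflammatory cytokine interleukin-6 (chromosome 7, 22725884 to 22732002, plus strand), rose 17.0-fold at 1 h, from 2.56 ± 0.338 to 59.6 ± 6.17 (SD, n = 5 each; log2 4.09, SE 0.23, adjusted p = 5.73e-32). RGS2, an inhibitor of Gq signalling, rose 10.4-fold at 1 h from 8.62 ± 3.09 to 96.5 ± 15.1 (SD, n = 5 each; log2 3.38, SE 0.18, adjusted p = 1.03e-33). DUSP1, a phosphatase that acts on MAP kinases, rose 9.0-fold at 1 h from 51.1 ± 5.88 to 480 ± 137 (SD, n = 5 each; log2 3.17, SE 0.18, adjusted p = 2.51e-32). PDE10A, a phosphodiesterase that breaks down cyclic nucleotides, rose 11.6-fold at 2 h from 13.6 ± 4.33 to 163 ± 19.4 (SD, n = 5 each).

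The remaining rises of the naming rule were those of SGK1, a kinase that regulates ion transport (log2 3.95 at 1 h), NR4A2 (3.71 at 1 h), CRISPLD2 (3.69 at 2 h), DMBT1, an epithelial defence protein (3.64 at 2 h), and RHOB, a small GTPase (3.32 at 2 h). SIK1B (3.76) and SIK1 (3.60), which encode salt-inducible kinases, rose at 1 h and are near-identical copies, so the values of each are uncertain. Among the falls were those of EGR1 at 1 h (log2 -2.66, SE 0.58, adjusted p = 0.00121), from 58.1 ± 44.0 to 8.96 ± 8.96 (SD, n = 5 each), and of FOSL1, an AP-1 subunit, at 2 h (log2 -1.77, SE 0.20, adjusted p = 6.69e-13), from 75.6 ± 10.1 to 21.5 ± 4.40 (SD, n = 5 each). The call of EGR1 ended with each time fitted alone (adjusted p = 0.649) and with the compared groups only (adjusted p = 0.352). TXNIP, an inhibitor of thioredoxin, fell at 2 h (log2 -1.54). F3, the gene of tissue factor (-1.72), OXTR, the oxytocin receptor gene (-1.37), and ANKRD1 (-1.36) fell at 6 h. NPPB, the gene of the B-type natriuretic peptide, fell at 18 h (-1.40, adjusted p = 0.00106), from 72.5 ± 13.5 (SD, n = 4) to 27.8 ± 10.2 (SD, n = 5), a call that ended without replicate 4 (adjusted p = 0.176) and with the compared groups only (adjusted p = 0.481). The 5S ribosomal pseudogene RNA5SP283 fell at 2 h (-2.80, adjusted p = 0.0459), and its call ended without replicate 1, 2, 4 or 5, with a pseudocount of 0.1, without a filter on low values, with each time fitted alone and with the compared groups only.

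Among the lists, 13 of 19 measured genes of the cyclic AMP and CREB list rose with indacaterol at 1 h and 0 fell, the same numbers adjusted over the list alone (camera adjusted p = 4.44e-106, and 2.17e-14 with an estimated correlation). At 2 h 14 rose, or 15 adjusted over the list alone (camera adjusted p = 1.75e-65, and 7.48e-10 with an estimated correlation), and at 6 h 3 rose, or 4 adjusted over the list alone (camera adjusted p = 9.16e-12, and 0.0254 with an estimated correlation). Of 12 cytokine genes 5 rose at 1 h, or 6 adjusted over the list alone (camera adjusted p = 2.73e-31, and 6.74e-13 with an estimated correlation), among them IL6, CXCL2 (log2 2.56), a neutrophil-attracting chemokine, and LIF (1.59 from 4.81 ± 1.43 to 16.2 ± 2.84, SD, n = 5 each). IL11 rose at 2 h (log2 3.09, adjusted p = 6.05e-17), from 15.9 ± 4.45 to 146 ± 47.9 (SD, n = 5 each), and at that time 4 cytokine genes rose, or 5 adjusted over the list alone (camera adjusted p = 8.45e-10, and 7.87e-05 with an estimated correlation). Of the immediate early genes 11 of 22 rose at 1 h and 2 fell, or 15 and 3 adjusted over the list alone (camera adjusted p = 2.12e-40, and 1.93e-06 with an estimated correlation).

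Of 29 glucocorticoid target genes 7 rose with indacaterol at 1 h and 1 fell, or 9 and 1 adjusted over the list alone (camera adjusted p = 2.52e-21, and 3.69e-07 with an estimated correlation). Those with the largest changes included DUSP1 and PER1 (log2 1.60 at 1 h), which the cyclic AMP list also holds. Of 27 cell cycle genes 3 fell at 2 h and 0 rose, or 5 and 0 adjusted over the list alone (camera adjusted p = 1.08e-06, and 0.0153 with an estimated correlation). These 3 encode mitotic regulators: PLK1 (log2 -0.93, adjusted p = 1.44e-09) fell from 142 ± 16.7 to 74.3 ± 7.08 (SD, n = 5 each), and AURKA and CCNB1 fell to 66.7 ± 11.3 and 187 ± 24.7 (SD, n = 5 each). KRT17, a keratin gene of the epithelial list, rose 7.14-fold at 2 h from 565 ± 181 to 3954 ± 772 (SD, n = 5 each). Of 20 cholesterol synthesis genes 2 fell at 6 h, or 3 adjusted over the list alone (camera adjusted p = 5.36e-07, but adjusted p = 0.465 with an estimated correlation).

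Over all genes limma called 193 higher and 15 lower with indacaterol at 1 h, 444 and 135 at 2 h, 139 and 119 at 6 h, and 20 and 10 at 18 h. At least 2-fold higher were 99, 195, 53 and 8 of these. 773 genes were called at 1 time or more, and 7 at all 4 times, all of them higher. The block gave 1090 calls at 2 h and 85 at 18 h, where the pairing check was met. With only the indacaterol and vehicle libraries in the fit the counts were 83 at 1 h, 313 at 2 h and 1 at 18 h, and with each time fitted alone 133 at 1 h. Without replicate 2 they were 136 at 1 h, 143 at 6 h and 11 at 18 h, without replicate 4 137 at 1 h, and without replicate 3 or 5 15 or 18 at 18 h. With library composition as covariates they were 987, 569 and 55 at 2, 6 and 18 h, and without a filter on low values 71 at 18 h.

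**Figure D2:**
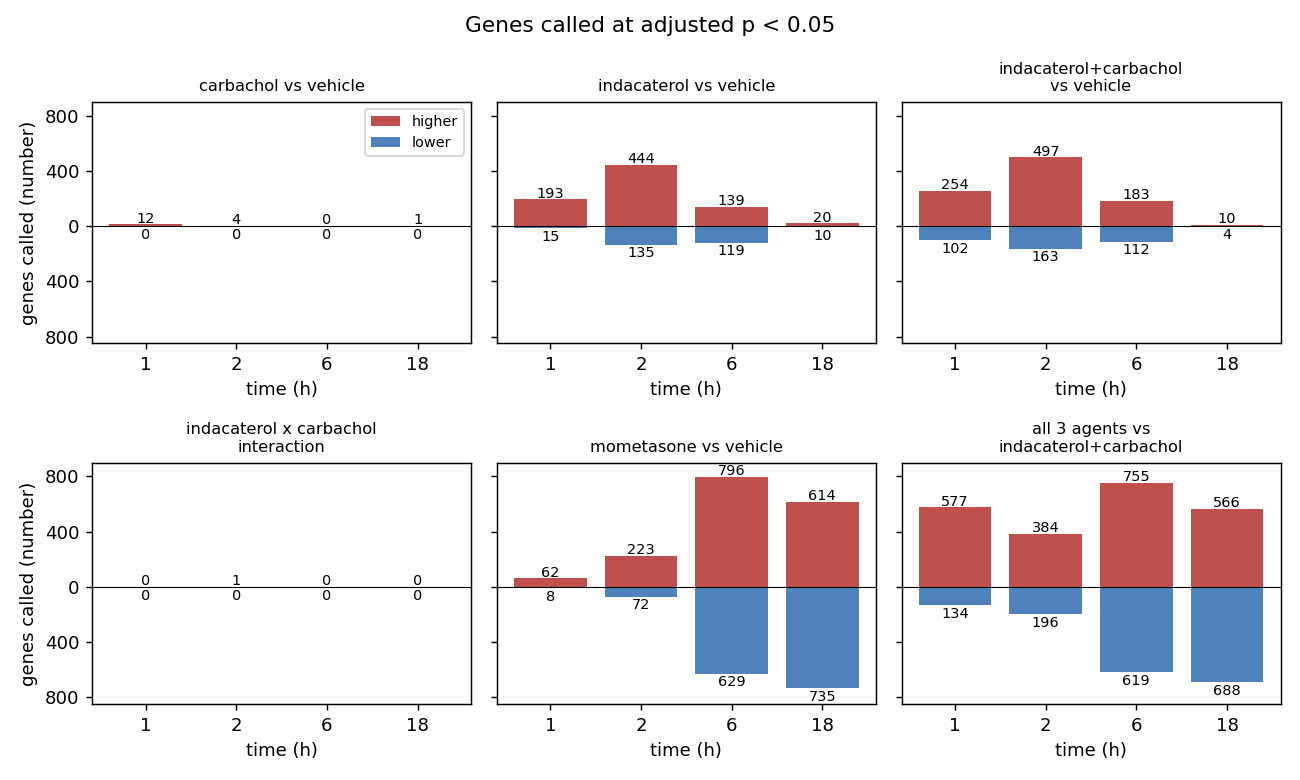
Genes called higher and lower by limma (adjusted p below 0.05) in each main comparison at each time of treatment, as numbers of genes, with higher genes drawn upward and lower genes downward. Carbachol alone called 12, 4, 0 and 1 genes at 1, 2, 6 and 18 h, indacaterol 208, 579, 258 and 30, and mometasone 70, 295, 1425 and 1349.

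The series asks how carbachol and indacaterol signalling interact, and the combination was compared with each agent. With both agents NR4A1 reached 249 ± 45.1 at 1 h (SD, n = 5), against 101 ± 31.2 with indacaterol and 73.5 ± 31.9 with carbachol (SD, n = 5 each). On the log2 scale the combined change of 4.30 lay below the sum of the 2 single changes by 1.15, a difference that did not pass (interaction log2 -1.15, adjusted p = 0.201). In deposited values the rise of NR4A1 from 11.9 with vehicle to 249 exceeded the 2 single rises together, so the sign depends on the scale. FOSB gave a log2 change of 3.03 with both, 1.89 with indacaterol and 2.19 with carbachol (interaction log2 -1.05, adjusted p = 0.299). For NAB2 at 2 h the signs of the single agents were opposite: the log2 change was 1.04 with carbachol, -0.51 with indacaterol (adjusted p = 0.0152) and -0.14 with both (adjusted p = 0.942), and the interaction did not pass (log2 -0.67, adjusted p = 1). RNF227 at 2 h likewise rose with carbachol, fell with indacaterol (log2 -0.39, adjusted p = 0.0395) and fell with both (-0.44, adjusted p = 0.0111). EGR1 at 1 h was at log2 -1.83 with both agents (adjusted p = 0.0711).

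The only gene called for the interaction at any time in the reported fit was TCIM, a regulator of Wnt/β-catenin signalling (TC1; chromosome 8, 40153455 to 40155308, plus strand), at 2 h. It stood at 0.0220 ± 0.0303 with vehicle, 1.67 ± 0.304 with indacaterol and 3.88 ± 0.640 with both agents (SD, n = 5 each), while its log2 change with carbachol alone was 0.04. The interaction was 0.82 (SE 0.14, adjusted p = 9.13e-04), in 5 of 5 pairs, and at 1 h TCIM rose by log2 1.69 with both agents. With a pseudocount of 0.1 the interaction log2 was 0.89 (adjusted p = 1), so the call of this low gene rests on the pseudocount of 1, and it also ended without replicate 1 (adjusted p = 0.112) or replicate 4 (adjusted p = 0.265) and with the compared groups only (adjusted p = 0.155). In limma 0 genes passed the interaction test at 1, 6 and 18 h, with 1520, 115 and 172 genes at an unadjusted p below 0.05. The count at 1 h was 6 without replicate 4 and 0 without any other replicate, and it was 1 without the libraries with over 20% mitochondrial RNA. With the replicate block the count at 1 h was far higher, and it is given with the alternative fits below. The pairing check was not met there, with 25 of 30 same-numbered pairs above its limit of 0.1. The count at 1 h thus depends on the fit. Among the lists the 13 calcium and NFAT genes lay below the sum of the single agents' log2 changes at 2 h as a group, with 0 members called over all genes or adjusted over the list alone (median log2 -0.14, camera adjusted p = 6.92e-04, and 0.00388 with an estimated correlation).

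Both agents together called 254 genes higher and 102 lower than vehicle at 1 h, 497 and 163 at 2 h, 183 and 112 at 6 h, and 10 and 4 at 18 h. With the replicate block these totals of 356, 660, 295 and 14 became 1429, 1273, 845 and 68, and with library composition as covariates 1194, 618 and 37 at 2, 6 and 18 h. They fell to 99, 329 and 0 at 1, 2 and 18 h with the compared groups only, and to 178 at 1 h with each time fitted alone. Without replicate 2 they were 161, 165 and 4 at 1, 6 and 18 h, without replicate 4 161 and 169 at 1 and 6 h, without replicate 5 605 at 1 h, and without replicate 3 9 at 18 h. At 18 h the total was 76 without a filter on low values and 9 with the stricter one. The largest changes of the immediate early list at 1 h were NR4A3 (log2 5.35), NR4A2 (5.08) and NR4A1 (4.30), and 12 of its 22 members rose and 0 fell, or 16 and 3 adjusted over the list alone (camera adjusted p = 1.44e-44, and 5.85e-07 with an estimated correlation). IL6 rose 27.4-fold at 1 h to 97.8 ± 20.8 (SD, n = 5). Of the genes higher with indacaterol alone, 167 were also higher with both agents at 1 h, 403 at 2 h, 125 at 6 h and 8 at 18 h, where independent lists would share 3.31, 14.9, 1.72 and 0.0135. Both comparisons use the same vehicle libraries, and part of the overlap may come from them. In 100 simulations unchanged groups had at most 1 gene called higher and so shared 0, which gives no baseline for lists of called genes. With the vehicle libraries divided between the 2 comparisons, the shared genes numbered 108 and 124 at 1 h, 249 and 260 at 2 h, 69 and 73 at 6 h, and 3 and 3 at 18 h. The division follows replicate numbers and leaves fewer vehicle libraries to each comparison, so the lower counts cannot be laid to the shared vehicle alone. Against indacaterol alone, adding carbachol called 6 genes higher and 7 lower at 1 h, and 1, TCIM, at 2 h. At 6 and 18 h limma called 0, with 147 and 172 at an unadjusted p below 0.05.

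Of the 12 genes higher with carbachol at 1 h, 6 were also higher with indacaterol (DUSP5, FOSB, JUNB, LURAP1L, NR4A1 and PER1), where independent lists would share 0.156. The simulated unchanged groups shared 0, which gives no baseline here either, and with the vehicle libraries divided 3 and 4 were shared. At 2 h 1 was shared, NR4A1 (0 and 1 with the vehicle libraries divided), and NAB2 and RNF227 were called in opposite directions. The changes with the 2 agents correlated across genes at r = 0.382 at 1 h, 0.242 at 2 h, 0.318 at 6 h and 0.467 at 18 h, and genes are not independent replicates. Both comparisons use the same vehicle libraries. Simulated unchanged groups that also shared a vehicle, drawn from the libraries of all treatments, gave a median r of 0.510, 0.519, 0.529 and 0.496. The covariance was 0.0177, 0.0121, 0.0106 and 0.0155, against simulated medians of 0.0132, 0.0127, 0.0128 and 0.0146, and the highest of 100 simulations exceeded the observed covariance at every time. With the vehicle libraries divided between the 2 comparisons r was -0.105 and 0.167 at 1 h, 0.00203 and -0.00176 at 2 h, -0.0323 and -0.0318 at 6 h, and -0.358 and -0.406 at 18 h. This division follows replicate numbers, whose libraries deviate together, so it may itself lower r and cannot isolate the effect of the shared vehicle.

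Mometasone alone raised classical glucocorticoid targets from 1 h on. TSC22D3 (chromosome X, 107713221 to 107777342, minus strand) rose 55.2-fold at 6 h, from 7.91 ± 1.95 to 484 ± 48.4 (SD, n = 5 each; log2 5.79, SE 0.22, adjusted p = 1.50e-47). CEBPB, a transcription factor gene of the acute phase response, rose 14.2-fold at 2 h from 18.9 ± 3.59 to 280 ± 41.3 (SD, n = 5 each; log2 3.83, SE 0.24, adjusted p = 1.66e-28). CNR1, the cannabinoid receptor 1 gene, rose 35.5-fold at 18 h to 38.7 ± 5.55 (SD, n = 3; log2 5.15, SE 0.28, adjusted p = 1.87e-32). SAA1, an acute phase protein gene, rose 30.4-fold at 18 h from 3.49 ± 2.31 (SD, n = 4) to 123 ± 20.2 (SD, n = 3). NPPB (chromosome 1, 11857464 to 11858931, minus strand) fell 27.1-fold at 18 h, from 72.5 ± 13.5 (SD, n = 4) to 1.68 ± 0.116 (SD, n = 3; log2 -4.76, SE 0.30, adjusted p = 1.12e-27).

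At 6 h the naming rule also gave rises of MARCHF10 (log2 4.08), RGCC, a cell cycle regulator (4.0), IP6K3, an inositol phosphate kinase (3.73), and the metallothionein genes MT1X (4.05) and MT1E (3.57). At 18 h it gave CYP4B1, a cytochrome P450 (5.10), AOX1, an aldehyde oxidase (3.94), and SCNN1A, the α subunit of the epithelial sodium channel (3.54). Beside NPPB it gave falls at 18 h of CPA4 (-3.60), from 90.6 ± 48.2 (SD, n = 4) to 5.98 ± 0.816 (SD, n = 3), CPA3 (-2.93), NOG, an antagonist of bone morphogenetic proteins (-2.94), and the pregnancy-specific glycoprotein genes PSG9 (-2.80), PSG5 (-2.80) and PSG2 (-2.76). F3 fell at 6 h (-2.97) from 109 ± 53.4 to 12.1 ± 2.70 (SD, n = 5 each). The metallothionein and PSG genes belong to families of close copies, so the value of each single member is uncertain. NR3C1 gave -0.76 at 6 h (adjusted p = 0.0818) and -0.53 at 18 h (adjusted p = 0.426), which did not pass.

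Of 29 glucocorticoid target genes 14 rose with mometasone at 1 h, 22 at 2 h, 25 at 6 h and 23 at 18 h, and 0 fell at any time. Adjusted over the list alone these were 19, 27, 25 and 24 (camera adjusted p = 6.06e-100, 2.72e-183, 1.67e-78 and 4.87e-44, all kept with an estimated correlation, the highest there being 5.71e-13). PER1 rose 9.94-fold at 2 h to 206 ± 19.7 (SD, n = 5), and DUSP1 7.15-fold from 49.4 ± 4.80 to 359 ± 37.8 (SD, n = 5 each). FKBP5, a co-chaperone of steroid receptors, rose 7.39-fold at 18 h to 152 ± 6.75 (SD, n = 3). Among the cytokines CCL2, a monocyte-attracting chemokine, fell at 6 h (log2 -2.35, adjusted p = 4.44e-20) from 62.0 ± 5.93 to 12.1 ± 5.27 (SD, n = 5 each), with IL6 (-1.48) and LIF. At 2 h 3 of 12 cytokine genes fell, or 4 adjusted over the list alone (camera adjusted p = 3.44e-04, and 0.0296 with an estimated correlation, but 0.0642 with that and the block). At 6 h 3 fell, or 4 adjusted over the list alone (camera adjusted p = 0.0148, but adjusted p = 0.195 with an estimated correlation).

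Of 11 genes of NF-κB feedback 2 rose with mometasone at 2 h and 1 fell, or 3 and 1 adjusted over the list alone. The list's median log2 change was -0.10 and its mean 0.42, and its test pointed up (camera adjusted p = 3.47e-04, and 0.0217 with an estimated correlation, but 0.111 with that and the block). The members that rose were BIRC3, an inhibitor of apoptosis (log2 3.16), and NFKBIA, which encodes the inhibitor IκBα (2.48, from 22.5 ± 2.52 to 130 ± 12.5, SD, n = 5 each). Of 21 genes of matrix remodelling 9 fell at 18 h and 1 rose, or 12 and 1 adjusted over the list alone (camera adjusted p = 0.00128, and 0.0214 with an estimated correlation). Among those that fell were LOXL2, a lysyl oxidase (-1.39), and MMP1, a collagenase (-1.25). Of 13 epithelial genes 5 fell at 18 h and 1 rose, the same numbers adjusted over the list alone (camera adjusted p = 0.00298, and 0.0401 with an estimated correlation), with KRT17 at 115 ± 32.2 (SD, n = 3) against 563 ± 112 (SD, n = 4) and KRT5, a basal cell keratin, higher (log2 1.21). Of 12 RGS genes, regulators of G protein signalling, 4 fell at 18 h, the same number adjusted over the list alone: RGS3, RGS7, RGS20 and RGS4. Their list's median log2 change was 0.02 and its mean -0.24, and its test pointed down (camera adjusted p = 0.0298, and 0.0492 with an estimated correlation). Of 20 cholesterol synthesis genes 3 fell at 6 h, or 5 adjusted over the list alone (camera adjusted p = 3.90e-04, but adjusted p = 0.659 with an estimated correlation).

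Over all genes limma called 62 higher and 8 lower with mometasone at 1 h, 223 and 72 at 2 h, 796 and 629 at 6 h, and 614 and 735 at 18 h. 42 genes were called at all 4 times, 37 of them higher and 5 lower each time. With the replicate block the counts were 124 at 1 h and 530 at 2 h. Without replicate 2 the total was 41 at 1 h, 891 at 6 h and 747 at 18 h, and without replicate 4 38 at 1 h. It was 18 at 1 h and 564 at 18 h with the compared groups only, 41 at 1 h with each time fitted alone, 117 at 1 h without a filter on low values, and 447, 2600 and 2448 at 2, 6 and 18 h with library composition as covariates.

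The comparison of all 3 agents with indacaterol and carbachol gives the effect of mometasone in cells stimulated by both agonists. TSC22D3 rose 97.1-fold at 6 h, from 6.81 ± 1.43 to 756 ± 131 (SD, n = 5 each; log2 6.60, SE 0.22, adjusted p = 1.39e-53). PLA2G4A, a phospholipase that releases arachidonic acid, rose 12.5-fold at 6 h from 1.07 ± 0.335 to 24.8 ± 3.29 (SD, n = 5 each; log2 3.65, SE 0.15, adjusted p = 1.86e-44). CCL2 (chromosome 17, 34255218 to 34257203, plus strand) fell 14.7-fold at 6 h, from 211 ± 55.2 to 13.2 ± 2.31 (SD, n = 5 each; log2 -3.88, SE 0.19, adjusted p = 4.69e-37). IL6 fell 6.61-fold at 2 h, from 47.4 ± 18.7 to 6.20 ± 2.62 (SD, n = 5 each; log2 -2.72, SE 0.23, adjusted p = 5.21e-19).

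Further rises of the naming rule were CNR1 (log2 4.98), RGCC (4.68), MT1X (4.47) and PDK4, a kinase that inhibits pyruvate dehydrogenase (3.59), at 6 h. ANKRD1 rose at 2 h (3.63, from 15.6 ± 5.14 to 212 ± 85.5, SD, n = 5 each), and CYP4B1 (4.55), MARCHF10 (4.53), AOX1 (4.01) and SAA1 (3.97) rose at 18 h. At 18 h CPA4 (-3.56), PSG5 (-2.98), NPPB (-2.89), TM4SF1 (-2.86) and PSG1 (-2.71) fell. RGS2 rose 6.65-fold at 6 h from 15.9 ± 2.79 to 112 ± 20.2 (SD, n = 5 each). NR3C1 fell at 6 h (log2 -1.11, adjusted p = 0.00348), from 51.3 ± 16.5 to 22.7 ± 4.73 (SD, n = 5 each), and at 18 h (-1.06, adjusted p = 0.0370).

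Of the 29 glucocorticoid target genes 18, 22, 25 and 24 rose at 1, 2, 6 and 18 h in these stimulated cells and 0 fell. Adjusted over the list alone these were 21, 25, 25 and 24 (camera adjusted p = 2.58e-44, 2.73e-98, 3.38e-84 and 4.14e-47, all kept with an estimated correlation). Of 12 cytokine genes 4 fell at 2 h and 0 rose, or 6 and 2 adjusted over the list alone (camera adjusted p = 1.71e-09, and 1.07e-04 with an estimated correlation). IL11 fell at 2 h from 145 ± 38.6 to 25.3 ± 7.93 (SD, n = 5 each; log2 -2.49, adjusted p = 4.74e-12). At 6 h 4 cytokine genes fell, the same number adjusted over the list alone (camera adjusted p = 1.78e-04, and 0.0230 with an estimated correlation, but 0.0654 with that and the block), and at 18 h 3 fell, or 4 adjusted over the list alone (camera adjusted p = 6.82e-04, and 0.0420 with an estimated correlation, but 0.111 with that and the block). At 18 h 5 of 13 epithelial genes fell and 1 rose, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.00147, and 0.0254 with an estimated correlation), KRT17 (log2 -1.88), KRT80 (-1.49) and CDH1 (-1.28) among them. Of 14 mesenchymal genes 3 fell at 18 h and 0 rose, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.00554, and 0.0492 with an estimated correlation, but 0.134 with that and the block), namely the collagen genes COL3A1 (log2 -1.39) and COL1A1 (-0.78) and the surface marker THY1 (-1.33). Of 20 cholesterol synthesis genes 6 fell at 18 h, or 8 adjusted over the list alone (camera adjusted p = 1.04e-05, but adjusted p = 0.554 with an estimated correlation).

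Over all genes limma called 577 higher and 134 lower at 1 h, 384 and 196 at 2 h, 755 and 619 at 6 h, and 566 and 688 at 18 h. With the replicate block the counts were 1107 at 2 h, 2616 at 6 h and 2412 at 18 h. At 1 h the total of 711 moved with the libraries used: it was 181 without replicate 1, 286 without replicate 2, 287 without replicate 4, 2113 without replicate 5, 321 without the libraries with over 20% mitochondrial RNA and 308 with each time fitted alone. With the compared groups only the totals were 42, 320 and 455 at 1, 2 and 18 h, with library composition as covariates 378, 1053, 2268 and 2103 at the 4 times, and without replicate 2 728 at 18 h. At 1 h the 13 mitochondrially encoded transcripts had a median log2 change of 0.71 in that comparison, with 0 called in limma over all genes or adjusted over the list alone (camera adjusted p = 3.98e-04, but adjusted p = 0.621 with an estimated correlation). Genes higher in this comparison and with mometasone alone numbered 50, 176, 518 and 364 at 1, 2, 6 and 18 h, where independent lists would share 2.41, 5.78, 40.5 and 23.4. Genes lower in both numbered 6, 52, 418 and 485, where independent lists would share 0.0723, 0.952, 26.3 and 34.1.

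**Figure D3:**
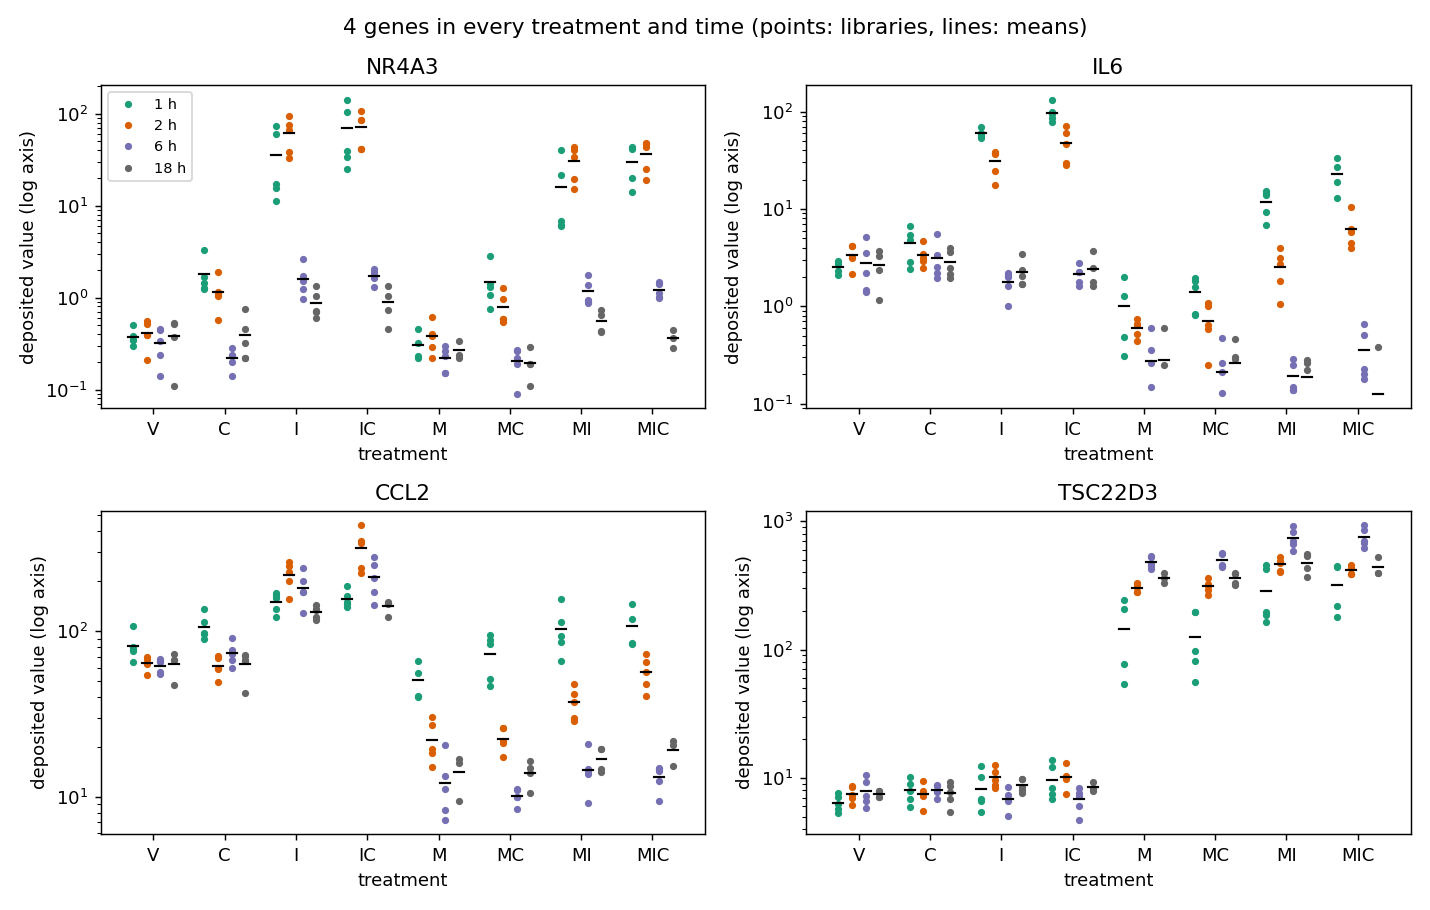
Values of NR4A3, IL6, CCL2 and TSC22D3 on a log axis in each library of the 8 treatments (V, vehicle; C, carbachol; I, indacaterol; IC, indacaterol with carbachol; M, mometasone; MC, mometasone with carbachol; MI, mometasone with indacaterol; MIC, all 3 agents) at the 4 times, with 1 point per library and lines for the means over all libraries of a group; 7 libraries listed at 0 for IL6 are not drawn. At 6 h CCL2 had a mean of 62.0 with V, 211 with IC and 13.2 with MIC.

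Genes induced by an agonist alone were followed in the comparison of all 3 agents with both agonists, which uses other libraries. Of 99 genes at least 2-fold higher with indacaterol alone at 1 h, mometasone lowered 19 and raised 21. At 2 h it lowered 45 and raised 39 of 195, at 6 h it lowered 22 and raised 15 of 53, and at 18 h it lowered 3 and raised 2 of 8. Of these genes 13, 33, 17 and 2 were also higher and 3, 14, 9 and 2 lower with mometasone alone. Mometasone alone was compared with the same vehicle libraries that chose these genes, which favours genes higher in both. Over all 14827 genes tested, 62, 223, 796 and 614 were higher and 8, 72, 629 and 735 lower with mometasone alone. With the genes chosen again in each fit, mometasone at 1 h lowered 10 and raised 10 without replicate 2, 8 and 13 without replicate 4, 12 and 11 with each time fitted alone, and 3 and 4 with the compared groups only. At 2 h it lowered 68 with library composition as covariates. At 18 h it lowered 1 without replicate 2, raised 4 with a pseudocount of 0.1, and lowered 0 and raised 0 with the compared groups only. Among all other genes tested it lowered 0.781%, 1.03%, 4.04% and 4.62% and raised 3.78%, 2.36%, 5.01% and 3.81%. Of the 4 genes at least 2-fold higher with carbachol alone at 1 h (NR4A1, FOSB, CCN2 and the pseudogene SPINT5P) mometasone lowered 1, FOSB (log2 -1.08, SE 0.30, adjusted p = 0.0173), and raised 0. The call of FOSB ended with a pseudocount of 0.1, with each time fitted alone, without libraries over 20% mitochondrial, with library composition as covariates, with the compared groups only, and without replicate 1, 2 or 4 (adjusted p from 0.0622 to 0.211). It raised 1 of the genes so chosen without replicate 2, 3 or 4, with a pseudocount of 0.1, the stricter filter, rescaled libraries or the covariates. Of the 2 at 2 h (NR4A1 and NAB2) it lowered 0 and raised 0, and it lowered 1 with the replicate block, with each time fitted alone or with the covariates.

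The remaining combinations were counted only. Against vehicle, mometasone with indacaterol called 362, 1135, 2626 and 1924 genes at 1, 2, 6 and 18 h, mometasone with carbachol 110, 328, 1509 and 1465, and all 3 agents 467, 1195, 2254 and 1595. Adding carbachol to mometasone called 5 genes at 1 h and 1 at 2 h, the latter being NAB2, and those at 1 h included NR4A1, FOSB and DUSP5. At 6 and 18 h limma called 0, with 164 and 140 at an unadjusted p below 0.05. The interaction of mometasone and carbachol called 0 genes in limma at each time, with 575, 112, 105 and 134 at an unadjusted p below 0.05. That of mometasone and indacaterol called 11, 60, 32 and 10 genes. The lists of the receptors of the agents with their kinases and effectors, of mucins and ion channels, and of markers of other cell types (7 measured) gave no camera call in any of the 6 main comparisons at any of the 4 times.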

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

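The tests of library composition, of single libraries and of scaling were chosen after the patterns they address were seen but before their own results were, and those of splits of the samples and of an effect of carbachol on the indacaterol response, and the choice of 1 difference between times per gene, after their results.

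Single libraries stood apart from the rest of their group in Dixon's test for 11 of 125 gene and group pairs, where chance gives about 1 in 20. With carbachol at 1 h FOSB stood at 32.75 in replicate 3 (next 8.44) and PER1 at 45.88 in replicate 1 (next 34.9). FOSB stood at 1.83 in vehicle replicate 3 at 1 h (next 1.02), and RNF227 at 15.84 in vehicle replicate 1 at 2 h (next 11.65). In the vehicle libraries at 18 h NPPB was low in replicate 2 at 52.26 (next 78), SCNN1A was high in replicate 3 at 2.12 (next 1.32), and CPA4 was high in replicate 3 at 162.4 (next 73.39). FOSL1 stood at 29.2 in indacaterol replicate 2 at 2 h (next 20.71). At 6 h MT1X stood at 49.51 in replicate 5 with indacaterol and carbachol (next 36.02), MT1E at 51.11 in vehicle replicate 5 (next 30.76) and F3 at 16.85 in mometasone replicate 3 (next 11.61).

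The share of the summed values from mitochondrially encoded genes stood apart in 4 of 30 groups, each time in replicate 1. It was 27.7% with indacaterol at 2 h, 28.0% with mometasone and indacaterol at 6 h, 17.2% with mometasone and carbachol at 2 h and 28.3% with indacaterol and carbachol at 2 h, against a median of 10.96% over all libraries.

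Effects of a named gene at 2 times were compared in limma, and 186 of 420 such differences passed (adjusted p below 0.05), in 60 of 70 pairs of a gene and a comparison. The naming rule takes most genes at the time of their largest change, which favours a difference from other times, so these numbers are no independent evidence of one. In 0 of them were the effects called in opposite directions at both times. For each of the 60 the largest difference is given here as the log2 change at the later time minus that at the earlier. With carbachol these lay between 1 and 6 h for FOSB (-2.17). Others lay between 1 and 18 h for NR4A1 (-2.40) and PER1 (-1.15). Further ones lay between 2 and 18 h for NAB2 (-1.11). With indacaterol they lay between 1 and 6 h for IL6 (-4.44), DUSP1 (-2.86), F3 (-1.89), ANKRD1 (-1.37) and OXTR (-1.12). Others lay between 1 and 18 h for SGK1 (-3.97), NR4A2 (-3.59), SIK1B (-3.20), SIK1 (-2.95) and RGS2 (-2.94). Further ones lay between 2 and 18 h for NR4A3 (-4.93), CRISPLD2 (-3.38), RHOB (-3.14), DMBT1 (-2.57), PDE10A (-2.25), NPPB (-1.78), FOSL1 (1.45) and TXNIP (1.87). With mometasone they lay between 1 and 6 h for F3 (-2.50), TSC22D3 (1.74), RGCC (2.33), MT1E (2.38), MT1X (2.52), MARCHF10 (2.78) and IP6K3 (3.25). Others lay between 1 and 18 h for NPPB (-4.21), CPA4 (-3.46), NOG (-2.57), PSG2 (-2.41), SCNN1A (3.15), AOX1 (4.13), CYP4B1 (4.51), CNR1 (4.66) and SAA1 (4.69). Further ones lay between 2 and 18 h for CPA3 (-2.79), PSG5 (-2.60), PSG9 (-2.43) and CEBPB (-1.38). For all 3 agents against both agonists they lay between 1 and 6 h for CCL2 (-3.31), PDK4 (1.5), TSC22D3 (1.76), RGCC (2.32), PLA2G4A (3.67) and CNR1 (4.70). Others lay between 1 and 18 h for CPA4 (-3.78), NPPB (-2.95), PSG5 (-2.93), PSG1 (-2.63), TM4SF1 (-1.98), SAA1 (3.47), AOX1 (4.0) and CYP4B1 (4.16). The last were IL6 (1.51, between 2 and 6 h), ANKRD1 (-2.62) and MARCHF10 (2.19), both between 2 and 18 h, and MT1X (-2.25, between 6 and 18 h).

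At 1 h indacaterol with carbachol against carbachol called 983 genes, and indacaterol against vehicle 208, a ratio of 4.73. The excess was largely of lower genes, with 410 higher and 573 lower against 193 and 15. At least 2-fold higher were 97 against 99, and at least 2-fold lower 81 against 2. With the mitochondrial and ribosomal protein shares as covariates the ratio was lower, at 3.45 (959 against 278). A linear adjustment for these shares cannot exclude library composition as a source. A single library as the whole source is argued against, since the ratio stayed at 1.81 or above with each of the 20 libraries left out in turn. It depended on them nonetheless: it was 1.81 without carbachol replicate 1, a library with 22.4% mitochondrial values, and 13.4 without replicate 5 of indacaterol with carbachol. An effect of carbachol on the indacaterol response stays open, because the interaction at 1 h called 0 genes while 1520 had an unadjusted p below 0.05, and it called 6 without replicate 4 and 0 without any other replicate. With the replicate block the interaction called far more genes at 1 h, as given below, but the pairing check was not met there.

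Libraries with the same replicate number deviated together from their group means, with a median correlation of 0.346. After rescaling by median ratios the median was 0.347. A single factor per library hardly changes a correlation of log2 values across genes, so this cannot decide whether the authors' scaling is the source. Library composition may account for part of it, since with both shares as covariates the median fell to 0.179, which is still above the limit of 0.1 set beforehand. A difference between cultures, days or sequencing kits stays open and was not tested, as no label gives one. No biological explanation was tested.

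Other splits of the compared libraries, whatever their replicate numbers, were counted in the reported model, 100 for each result except 35 where groups were of 3 or 4. For 2 groups the 100 came from 126 possible splits, so a share near the limit, such as 4 of 100, could lie on either side of 0.05 over all of them. With carbachol at 1 h, 38 of the other splits called at least 1 gene. For carbachol against vehicle the share was below 0.05 at 1 h (12 genes, reached by 4 of 100 splits, highest other 16) and at 2 h (4 genes, 1 split, highest other 2), and not at 18 h (1 gene, 31 splits, highest other 3). At 6 h the count was 0 genes, which all 100 splits reach, so the count says nothing (highest other 1). For indacaterol against vehicle the share was below 0.05 at each time: 208 genes (1 split, highest other 121), 579 (2 splits, highest other 3522), 258 (1 split, highest other 58) and 30 (2 splits, highest other 43). The same holds for both agonists against vehicle, with 356 genes (4 splits, highest other 3306), 660 (2 splits, highest other 739), 295 (1 split, highest other 86) and 14 (1 of 35 splits, highest other 2). For the interaction of both agonists the share was not below 0.05 at 2 h (1 gene, 19 splits, highest other 366). At 1, 6 and 18 h it called 0 genes, which all 100 splits reach, so the count says nothing there (highest others 1140, 104 and 77).

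For mometasone against vehicle the share was below 0.05 at each time, with 70 genes (highest other 57), 295 (highest other 106), 1425 (highest other 557) and 1349 (highest other 1020), each reached by 1 split, the real one. For all 3 agents against both agonists the share was below 0.05 as well, with 711 genes (4 splits, highest other 5118), 580 (1 split, highest other 294), 1374 (1 split, highest other 522) and 1254 (1 of 35 splits, highest other 997). Splits that called several times the real number, such as 3522, 3306 and 5118, point to a structure of the samples.

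The splits above ignore the replicate numbers. Where these pair the libraries, the splits of 2 groups that part as many same-numbered pairs as the real one were 16, or 8 for both agonists and for all 3 agents at 18 h, which is too few for a share below 0.05. In these comparisons the shares above hold only against splits that ignore the pairs. Among the splits that keep them carbachol called 4 genes in the real split and 1 in the highest other at 2 h, 0 and 0 at 6 h, and 1 and 1 at 18 h, and indacaterol called 579 and 205 at 2 h and 30 and 11 at 18 h. Both agonists called 356 and 145, 660 and 221, 295 and 52, and 14 and 0 at 1, 2, 6 and 18 h. Mometasone called 70 and 35 at 1 h and 295 and 92 at 2 h, and all 3 agents called 580 and 189, 1374 and 433, and 1254 and 571 at 2, 6 and 18 h. For the interaction, 25 of 100 splits within numbers called 1 gene or more at 2 h (highest other 404), and at 18 h the highest other was 13. In the paired comparisons of 2 groups the splits with more calls than the real one, such as 3522 and 3306, parted fewer pairs.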

How the results depend on the processing

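The fits without libraries over 20% mitochondrial, with library composition as covariates and with the compared groups only were chosen after the data were seen, and the other alternatives before. Of the 73 named gene results 0 reversed in any alternative. The naming rule takes called genes with the same direction in all pairs, which favours this. Fits that change only the filter, the times or the groups fitted keep the log2 changes, so they could not reverse one. All 73 stayed called with rescaled libraries, with the replicate block and with the covariates, 72 of 72 with the stricter filter, 72 without a filter, 70 with a pseudocount of 0.1, 70 without libraries over 20% mitochondrial, 63 with each time fitted alone, 57 with the compared groups only, and 65, 68, 67, 67 and 67 without replicates 1 to 5. TCIM did not pass the stricter filter and has no value there. Rescaling moved 0 of the 24 counts of calls by more than 1.5 times, and the block moved 20. The cause of the changes below was not tested, except that fits of fewer libraries have fewer residual degrees of freedom. Depth is unknown, so what it limits cannot be stated.

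Counts below are given for 1, 2, 6 and 18 h in turn or with their time, and only where they moved by more than 1.5 times. With the replicate block, carbachol against vehicle called 26 at 1 h, 23 at 2 h and 1 at 6 h, indacaterol 336, 1090, 755 and 85, both agonists 1429, 1273, 845 and 68, and their interaction 410 at 1 h. Mometasone called 124, 530, 2976 and 2561, and all 3 agents against both agonists 3785, 1107, 2616 and 2412. The pairing check was not met for carbachol at 1 h, indacaterol at 1 and 6 h, the interaction at 1 and 6 h, mometasone at 6 and 18 h, and all 3 agents at 1 h. There 7 of 10, 6 of 10, 5 of 10, 18 of 20, 16 of 20, 7 of 10, 2 of 6 and 5 of 8 libraries correlated best with their own number, a hint from the data and not the design. With the block, 105 in place of 106 gene list calls passed in the paired comparisons (6 lost, 5 gained), and with an estimated correlation 39 in place of 44 (8 lost, 3 gained). Lost at the preset correlation were clock genes, EGF receptor ligands and NF-κB feedback at 2 h and the cyclic AMP list at 6 h for all 3 agents, cytokines with both agonists at 18 h, and ribosomal proteins with mometasone at 1 h. Lost at the estimated one were the immediate early genes at 2 h with carbachol and with indacaterol, cytokines and NF-κB feedback with mometasone at 2 h, and for all 3 agents the calcium list at 2 h, cytokines at 6 and 18 h and mesenchymal genes at 18 h.

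With 1 replicate left out of every group, carbachol called 5 to 9 at 1 h, 1 to 3 at 2 h and 0 to 1 at 18 h. Indacaterol called 136 to 218 at 1 h, 143 to 261 at 6 h and 11 to 23 at 18 h, and both agonists 161 to 605 at 1 h, 165 to 286 at 6 h and 4 to 15 at 18 h. The interaction called 0 to 6 at 1 h, 0 to 1 at 2 h and 0 to 1 at 18 h. Mometasone called 38 to 78 at 1 h, 891 to 1464 at 6 h and 747 to 1324 at 18 h, and all 3 agents against both agonists 181 to 2113 at 1 h and 728 to 1217 at 18 h.

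With the compared groups only, carbachol called 0 at 1, 2 and 18 h, indacaterol 83 at 1 h, 313 at 2 h and 1 at 18 h, both agonists 99 at 1 h, 329 at 2 h and 0 at 18 h, the interaction 0 at 2 h, mometasone 18 at 1 h and 564 at 18 h, and all 3 agents against both agonists 42 at 1 h, 320 at 2 h and 455 at 18 h. With each time fitted alone, carbachol called 3 at 1 h, 1 at 2 h and 0 at 18 h, indacaterol 133, both agonists 178, mometasone 41 and all 3 agents 308, these at 1 h. With the covariates, carbachol called 9 at 2 h, indacaterol 987 at 2 h, 569 at 6 h and 55 at 18 h, both agonists 1194 at 2 h, 618 at 6 h and 37 at 18 h, mometasone 447 at 2 h, 2600 at 6 h and 2448 at 18 h, and all 3 agents against both agonists 378, 1053, 2268 and 2103. Without libraries over 20% mitochondrial, the interaction called 1 and all 3 agents 321 at 1 h.

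Without a filter on low values, carbachol called 8 at 2 h, 4 at 6 h and 39 at 18 h, indacaterol 71 and both agonists 76 at 18 h, the interaction 2 at 2 h, 1 at 6 h and 2 at 18 h, and mometasone 117 at 1 h. The stricter filter called 0 for carbachol at 18 h, 9 for both agonists at 18 h and 0 for the interaction at 2 h. A pseudocount of 0.1 called 0 for the interaction at 2 h and 1 at 6 h.

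Of the genes induced by carbachol, the number lowered by mometasone at 1 h was 0 to 1 with 1 replicate left out, 0 with a pseudocount of 0.1, 0 with each time fitted alone, 0 without libraries over 20% mitochondrial, 0 with the covariates and 0 with the compared groups only. At 2 h it was 1 with the replicate block, with each time fitted alone and with the covariates. The number raised at 1 h was 0 to 1 with 1 replicate left out, and 1 with a pseudocount of 0.1, the stricter filter, rescaling, the block and the covariates. Of those induced by indacaterol, the number lowered was 8 to 21 at 1 h and 1 to 4 at 18 h with 1 replicate left out, 30 at 1 h with the block, 12 at 1 h with each time fitted alone, 68 at 2 h with the covariates, and 3 at 1 h and 0 at 18 h with the compared groups only. The number raised was 10 to 26 at 1 h with 1 replicate left out, 11 at 1 h with each time fitted alone, 4 at 18 h with a pseudocount of 0.1, and 4 at 1 h and 0 at 18 h with the compared groups only.

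With an estimated correlation 64 in place of 154 gene list tests passed. With the vehicle libraries divided between the comparisons by replicate number, the correlation of carbachol and indacaterol changes was -0.105 and 0.167 at 1 h, 0.00203 and -0.00176 at 2 h, -0.0323 and -0.0318 at 6 h, and -0.358 and -0.406 at 18 h. As stated above, this division cannot isolate the shared vehicle.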

Other observations

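The genes below were picked after their values were seen, from the interaction of mometasone and indacaterol, which the report gives only as counts. At 1 h RASD1, a Ras-related GTPase gene, had a log2 change of 0.17 with mometasone (adjusted p = 0.993), rose by 0.58 with indacaterol (adjusted p = 0.00189) and by 2.50 with both, an interaction of 1.75 (SE 0.19, adjusted p = 1.86e-11 in limma, in 4 of 4 pairs). RBBP8NL at 2 h gave -0.02, 0.05 and 1.34 (interaction 1.31, adjusted p = 1.33e-13, in 5 of 5 pairs). HRK, which encodes a protein that promotes apoptosis, gave 1.62 with mometasone, 0.20 with indacaterol and 3.94 with both at 2 h (interaction 2.12, adjusted p = 1.91e-06). RGS2 at 6 h gave 1.12, 1.18 and 3.85 (interaction 1.55, in 5 of 5 pairs). CLDN1, a tight junction gene, was at -1.13, -0.35 and -0.10 at 6 h (interaction 1.38, in 5 of 5 pairs).

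Other genes lay below the sum of the log2 changes of the single drugs. A sum of log2 changes is a product of fold changes. A gene below it can still exceed the sum of the single rises in deposited values, so the sign depends on the scale. DUSP1 at 1 h gave log2 2.62 with mometasone, 3.17 with indacaterol and 4.10 with both (interaction -1.69, adjusted p = 9.16e-06, in 4 of 4 pairs), and SGK1 at 2 h gave 2.73, 3.55 and 3.96 (interaction -2.32). WWP2, a ubiquitin ligase gene, rose with indacaterol by 1.21 at 2 h, and with both drugs it stood at 0.06 (interaction -1.10). In all, 3 genes lay above and 8 below the sum at 1 h, 38 and 22 at 2 h, 22 and 10 at 6 h, and 7 and 3 at 18 h. With indacaterol and carbachol together in place of indacaterol, the interaction with mometasone had the same sign in 11 of 11, 59 of 60, 32 of 32 and 10 of 10 of these genes and was itself called in 7, 44, 25 and 5. The mometasone and vehicle libraries enter both interactions, so these numbers do not separate a shared effect from shared libraries.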
